A study of Mus musculus with 61 samples.

How the data were processed

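RNA sequencing libraries of sorted Thy1.2-positive retinal cells were compared between DBA/2J and D2-Gpnmb+ mice at 4 and 9 months, with a further 9-month DBA/2J group given nicotinamide. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.7 and Bowtie2 2.0.6 to the mouse build mm10 and counted per gene with HTSeq. The deposited values are a signal that the authors made by dividing gene read counts by a size of each library and multiplying to a common scale near counts per 1e6, without a logarithm. How that size was computed is not stated in the labels, and low genes had already been left out of the table. In every library 100% of the positive values were whole multiples of 1 step within a tolerance of 0.05, so whole reads could be recovered, and these were used for edgeR 4.0.16 and DESeq2 1.42.0. Recovered totals per library ran from 5133114 to 19501444 with a median of 9730486, and sums of the deposited values from 717752 to 1560902. The table had 15171 genes, and 22 with names that a spreadsheet had turned into dates were left out, which left 15149. Every gene had a read in at least 13 libraries. Pou4f2, Ddx3y and Tyrp1 were not among the genes. No library was a copy of another (lowest chi-squared per gene between 2 libraries 7.34).

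All 61 columns were used. Column names give the group and a library number, and they could be matched to the groups of the labels but not to single samples. The library numbers have gaps in the 9-month groups, and whether libraries had been left out of the table is not stated in the labels. The labels do not state whether libraries of a group came from separate animals, so p values measure the spread between these libraries. The columns were divided by hand into 3 blocks of 10, 18 and 33 libraries. Blocks 1 and 2 are 2 stretches in which DBA/2J columns of 9 months are followed by D2-Gpnmb+ columns of 9 months. Block 3 runs from the first nicotinamide column to the end, with 4- and 9-month columns mixed. Its nicotinamide, DBA/2J water and D2-Gpnmb+ columns follow each other as 3 stretches. Treatment and strain therefore follow column order inside block 3 as well. The division was made after the expression values were looked at, in which the first 10 columns stood apart, and its counts per group equal those of the 3 series of sample numbers in the labels. Sorted by sample number, the labels give the same order of groups as all 61 columns. If the columns follow the sample numbers, the 3 blocks are these 3 series. What the blocks stand for is not stated in the labels. Block 1 holds 6 libraries of DBA/2J and 4 of D2-Gpnmb+ at 9 months, block 2 holds 16 and 2, and block 3 holds 3 and 3 together with all others. The labels do not give sex by library.

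Comparisons, gene lists, the rule for named genes and alternatives were written before the data were examined. The plan named edgeR on counts. Because the deposited values are not counts, the test was changed to limma 3.58.1 in R 4.3.3, with a trended and robust empirical Bayes fit on log2 of the value plus 1. It used only the groups compared and genes with a value of at least 1 in as many libraries as the smallest group. Adjusted p values are Benjamini-Hochberg values with a threshold of 0.05. The edgeR quasi-likelihood test on the recovered reads became an added alternative, and it called 9, 36, 3152, 1501, 42, 2231, 1060 and 207 genes in the 8 comparisons in the order strain at 9 months, strain at 4 months, age in DBA/2J, age in D2-Gpnmb+, interaction, nicotinamide, nicotinamide against D2-Gpnmb+ and nicotinamide against 4 months. The last of these comparisons was added after the data were seen.

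There were 36 gene lists, 11 of cell type markers, 24 of pathways and 1 control, written from general knowledge of the genes. Lists with at least 5 tested genes were tested with camera on log2 of the value plus 2, with a preset correlation of 0.01 between genes. A second p value used a correlation estimated from the data, and no list in any comparison had an adjusted p under 0.05 with it in the pooled libraries. Within block 3, where this second test was added after the data were seen, 1 list did. Camera called 16 of 33 lists for strain at 9 months, 9 of 31 for strain at 4 months, 17 of 33 for age in DBA/2J, 17 of 31 for age in D2-Gpnmb+, 10 of 33 for the interaction, 17 of 33 for nicotinamide, 18 of 31 for nicotinamide against D2-Gpnmb+ and 10 of 31 for nicotinamide against 4 months. Genes of a list past the threshold are counted after adjustment over all genes and after adjustment over the list alone. Reads of paralogs such as ribosomal protein genes can be shared between gene copies by counting, so single values of such genes are uncertain.

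Named genes were, per comparison, the 10 largest increases and the 10 largest decreases with an adjusted p under 0.05 and a mean of at least 5 in the higher group, leaving out unnamed gene models. To these were added up to 4 members with the smallest adjusted p of each list that camera called or of which at least 25% passed. Gpnmb, Nampt, Nmnat1 to Nmnat3, Thy1, Rbpms, Pou4f1, Sncg and Xist were always eligible. Some genes that the rule names are not reported here. Genes outside this rule are marked in the text as chosen after their values were seen.

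Spread was the root mean square distance of a library from the mean of the other libraries of its group over the 2000 genes with the highest mean, on log2 of the value plus 2, tested by permutation. Correlations of effects were set against 100 random splits of the water libraries and against 100 simulations with no effect. To see whether chance can give the counts, libraries were split 100 times into groups of the same sizes. As an addition after the data were seen, group labels were permuted among the libraries of block 3 alone and the pooled and block 3 fits repeated, for 100 labellings that include the real one. Analyses of column blocks, other pseudocounts, scaling to total reads and edgeR were chosen after the data were seen.

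The test was checked on simulated data made from the libraries, with 100 genes shifted 2-fold and 100 shifted 4-fold. Shifted genes were drawn among those with a mean of at least 5. Counts were simulated independently, without blocks or mixtures of cell types. The shares called and the unchanged genes called therefore do not cover lower genes or differences between blocks. The share called at 2-fold and 4-fold was 71% and 100% for strain at 9 months (13600 genes), 97% and 100% for strain at 4 months (12695 genes), 78% and 98% for age in DBA/2J (13479 genes) and 66% and 98% for age in D2-Gpnmb+ (12767 genes). It was 53% and 87% for the interaction (14036 genes), 70% and 96% for nicotinamide (13766 genes), 53% and 94% for nicotinamide against D2-Gpnmb+ (12886 genes) and 90% and 100% for nicotinamide against 4 months (12909 genes). Between 4 and 13 unchanged genes were called per comparison. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.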

Results

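Gene expression was measured by RNA sequencing in sorted retinal cells of 2 mouse strains. DBA/2J mice develop pigment dispersion, raised eye pressure and glaucoma with age, in part through a mutation of Gpnmb. D2-Gpnmb+ mice have the same background with a functional Gpnmb allele and do not develop glaucoma. The sort kept Thy1.2-positive cells that lacked Cd11b, Cd11c, Cd34, Cd45.2 and GFAP, and the labels call them retinal ganglion cells, the neurons whose axons form the optic nerve. Eyes came from young animals of 4 months and from animals of 9 months, and the labels describe optic nerves free of detectable axon loss. The 61 libraries comprised 10 of DBA/2J and 10 of D2-Gpnmb+ at 4 months, and 25 of DBA/2J and 9 of D2-Gpnmb+ at 9 months, all on water. A further 7 were from DBA/2J at 9 months given nicotinamide, a vitamin precursor of NAD, at 500 mg per kg per day. Reads per library ranged from 5133114 to 19501444 in 9-month DBA/2J, from 7284988 to 14961078 in 9-month D2-Gpnmb+, and from 9136453 to 12218457 with nicotinamide. The 4-month libraries held 5449826 to 11016497 reads in DBA/2J and 7062913 to 11309143 in D2-Gpnmb+. Values are deposited normalised read counts, errors of group means are standard deviations and errors of log2 fold changes are standard errors. The columns of the table were divided after the data were seen into 3 stretches, called blocks 1, 2 and 3 here, with 10, 18 and 33 libraries. All 4-month and all nicotinamide libraries lie in block 3, which holds only 3 of the 25 libraries of DBA/2J on water at 9 months and 3 of the 9 of D2-Gpnmb+ at 9 months. Differences of age and of nicotinamide were therefore also computed within block 3. Those fits reuse libraries of the pooled fits, so a shared direction is not a replication.

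The sorted samples carried far more RNA of marker genes of photoreceptors, bipolar cells and Müller glia than of marker genes of ganglion cells. Gnat1, the rod transducin subunit, averaged 3796 over the 61 libraries. The rod bipolar genes Prkca (2432) and Trpm1 (1450.4) and the Müller glia enzyme Glul (1678) were also abundant. The ganglion cell genes Thy1 (29.4 ± 18.7), Rbpms (11.1 ± 4.60), Nefl (11.2 ± 10.1), Sncg (1.23 ± 1.5625) and Pou4f1 (0.580 ± 0.715) lay far lower. The median over 23 ganglion cell markers averaged 2.63 per library, against 288 for 17 rod markers, 281 for 14 bipolar markers, 116 for 15 Müller glia and astrocyte markers and 16.9 for 12 amacrine and horizontal cell markers. Markers of microglia and macrophages averaged 1.49. Xist, transcribed from the inactive X chromosome of females, averaged 7607 and was 7.93 in 1 library, D2-Gpnmb+ at 9 months replicate 8. Every comparison that follows therefore describes RNA with markers of several retinal cell types, and how that RNA entered the samples was not tested.

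**Figure D1:**
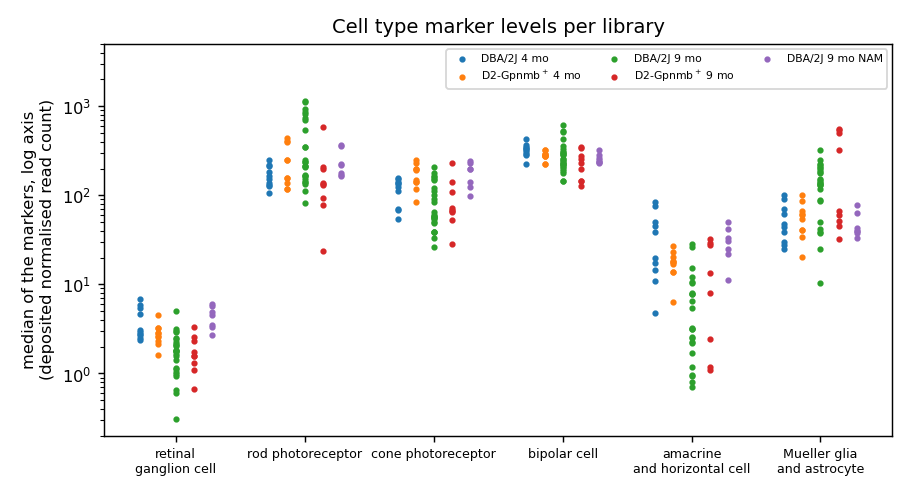
Each point is 1 library and shows the median deposited normalised read count over the markers of 1 cell type, on a log axis, for the 5 groups (NAM, nicotinamide). Ganglion cell markers lay below rod, cone, bipolar and Müller glia markers in all 61 libraries.

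The strain comparison at 4 months asked what differs before disease. Gpnmb, a transmembrane glycoprotein of pigment cells and macrophages that is truncated in DBA/2J, was the gene that fell most, and this matches the genotype that the labels give. Pde10a, a cyclic nucleotide phosphodiesterase, and Mpc1, a subunit of the carrier that brings pyruvate into mitochondria, rose. Sptssa, a subunit of the enzyme that starts sphingolipid synthesis, and the ribosomal protein gene Rps21 fell. Gpnmb (chromosome 6, 49036546 to 49070929, GRCm38) had 9.15 ± 3.38 in DBA/2J and 85.0 ± 30.96 in D2-Gpnmb+ (log2 fold change −3.06 ± 0.23, adjusted p 5.01e-08). The highest of the 10 DBA/2J libraries (14.5) lay below the lowest of the 10 D2-Gpnmb+ libraries (34.7). Of 12804 genes tested with limma, 32 passed an adjusted p of 0.05, 13 higher and 19 lower in DBA/2J. Pde10a (75.6 ± 14.97 against 27.3 ± 6.04, adjusted p 5.01e-08) and Mpc1 (7.23 ± 1.67 against 2.47 ± 0.848, adjusted p 8.24e-05) were the largest increases. The neurotransmitter transporter Slc6a17 (log2 fold change 0.87), the GABA-degrading enzyme Aldh5a1 (0.58), the sodium-proton exchanger Slc9a8 (0.52), the deubiquitinase Usp11 (0.51) and the amino acid transporter Slc43a2 (0.49) also rose. Besides Gpnmb, the lipid-binding glial gene Fabp7 (−0.94), the centrosomal gene Nin (−0.84), Sptssa (−0.82), the kinase Mapk4 (−0.76), the cone transducin subunit Gngt2 (−0.72), the growth factor response gene Etv5 (−0.70) and the ribosomal protein genes Rps21 (−0.69) and Rps23 (−0.43) fell. The counts rested in part on single libraries, with 6 genes past the threshold without DBA/2J replicate 4 and 92 without DBA/2J replicate 10. Gpnmb, Pde10a, Mpc1, Aldh5a1 and Slc43a2 passed in all 20 fits with 1 library left out, Sptssa in 19 and Mapk4 and Rps21 in 15. The calls of Slc6a17 (6 of 20), Slc9a8 (7), Usp11 (9), Fabp7 (9), Nin (8), Gngt2 (4), Etv5 (9) and Rps23 (8) ended in most fits.

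At 4 months cone markers were lower in DBA/2J as a list (median log2 fold change −0.66, camera adjusted p 2.01e-10), and the adjusted p with an estimated correlation was 0.281. Among cone genes, 1 passed over all genes and 8 of 10 when adjusted over the list alone, and Opn1sw had 408 ± 149 against 823 ± 258. Cytosolic ribosomal proteins were lower (median −0.24, camera adjusted p 1.57e-21, adjusted p with an estimated correlation 0.281), with 2 past the threshold over all genes and 35 of 72 adjusted over the list alone. The mitochondrially encoded subunits of oxidative phosphorylation were lower (median −0.75, camera adjusted p 2.01e-10, with an estimated correlation p 0.518), with 12 of 13 past the threshold adjusted over the list alone. Mitochondrial ribosomal RNA and Rn45s together made up 26.8 ± 5.02% of reads in DBA/2J and 35.0 ± 9.40% in D2-Gpnmb+. Rod markers were lower too (median −0.47, camera adjusted p 1.02e-08, with an estimated correlation p 0.566). Ganglion cell markers were higher (median 0.37, camera adjusted p 3.14e-04, with an estimated correlation p 0.518), with 2 adjusted over the list alone, and amacrine and horizontal cell markers were higher too (median 0.55, camera adjusted p 8.07e-04, with an estimated correlation p 0.732). Scaling to total reads moved the median of all genes by 0.24 log2 here and left 19 genes higher and 1 lower.

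**Figure D2:**
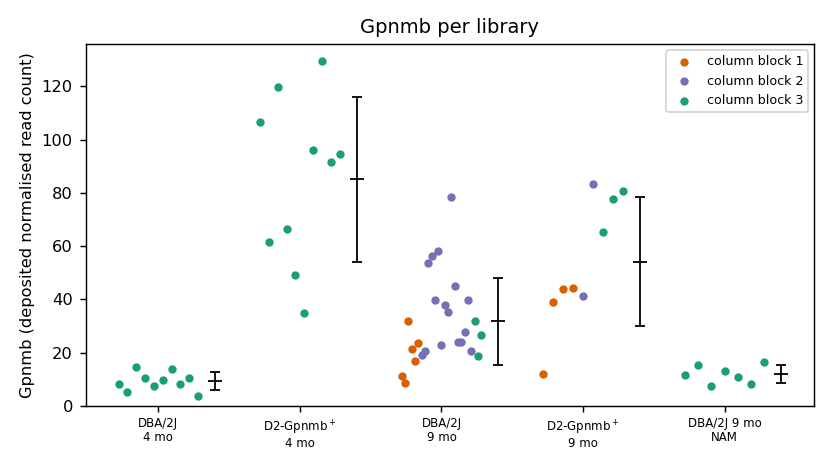
Each point is the deposited normalised read count of Gpnmb in 1 library, coloured by column block, and bars show the group mean and standard deviation. Gpnmb was 9.15 in DBA/2J and 85.0 in D2-Gpnmb+ at 4 months, and 31.7 and 54.2 at 9 months (NAM, nicotinamide).

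The strain comparison at 9 months asked how DBA/2J differs from its control when eye pressure is high but axons are still present. Only 3 of 13755 genes passed: Ptp4a3, a phosphatase that promotes cell migration, rose, and Pag1, a membrane adaptor that restrains Src kinases, and Irf2bp2, a repressor of inflammatory transcription in macrophages, fell. Ptp4a3 had 86.0 ± 29.4 against 44.4 ± 13.2 in D2-Gpnmb+ (log2 fold change 0.92 ± 0.18, adjusted p 0.0457). Pag1 had 47.1 ± 10.9 against 87.3 ± 33.2 (−0.81 ± 0.15, adjusted p 0.0457) and Irf2bp2 127 ± 27.6 against 196 ± 43.05 (−0.63 ± 0.12, adjusted p 0.0457). At an unadjusted p of 0.05, 1812 genes (13.2%) passed. The count was 55 without D2-Gpnmb+ replicate 9, 1 without replicate 13 or replicate 15, and 0 without any of the other 6 libraries of that group. With block as a covariate Pag1 (−0.73, adjusted p 0.0339) and Slc38a2 (−0.59, adjusted p 0.0448), an amino acid transporter chosen after its value was seen, passed, and Ptp4a3 and Irf2bp2 did not (both adjusted p 0.146). Within block 3 no gene passed by limma, with 873 at an unadjusted p of 0.05. DESeq2 called 332 genes and edgeR 9. Within block 1 alone, 6 DBA/2J and 4 D2-Gpnmb+ libraries gave 1635 genes, 614 higher and 1021 lower, a comparison added after the data were seen.

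Gpnmb itself did not pass at 9 months (31.7 ± 16.4 against 54.2 ± 24.1, log2 fold change −0.75 ± 0.28, adjusted p 0.216), and within block 3 its log2 fold change was −1.53 ± 0.21 (adjusted p 0.162). D2-Gpnmb+ replicate 1, a library of block 1, had only 11.9, against at least 38.9 in the rest of its group. That lies below the highest 4-month DBA/2J library (14.5), and the library was kept in the group that its column name gives. Rod genes were higher as a list (median 1.23, camera adjusted p 9.88e-15, with an estimated correlation p 0.241), with all 17 past the threshold adjusted over the list alone and none over all genes. Genes of nuclear-encoded oxidative phosphorylation subunits (median 0.50, camera adjusted p 9.53e-30, with an estimated correlation p 0.233) and of cytosolic ribosomal proteins (0.68, camera adjusted p 4.5e-44, with an estimated correlation p 0.233) were higher as well. Of these, 47 of 78 and 65 of 72 passed adjusted over the list alone. Microglia and macrophage markers such as Ptprc, Csf1r, Tyrobp and C1qb were higher as a list (median 1.42, camera adjusted p 9.74e-08, with an estimated correlation p 0.284), and complement C3, which tags synapses and cells for removal, had 8.16 ± 7.62 against 2.08 ± 2.02 (adjusted p 0.0987). Within block 3 the medians of the rod, oxidative phosphorylation, ribosomal and microglia lists were 0.04, 0.05, −0.05 and 0.05, so the list differences were not present there. Complement genes had a median of 0.61 (camera adjusted p 0.0131, with an estimated correlation p 0.233) and 0.32 in block 3. Pax6, a gene of amacrine cells, was lower in value (46.2 ± 21.5 against 90.1 ± 31.3, adjusted p 0.0987). The amacrine and horizontal cell list was lower in the pooled libraries (median −0.62, camera adjusted p 0.0231, with an estimated correlation p 0.429) and within block 3 (−0.61, camera adjusted p 6.84e-04, with an estimated correlation p 0.4932). The cholesterol and fatty acid synthesis list, with Sqle (23.8 ± 9.04 against 38.3 ± 18.6), Insig1 and Mvd, was lower in both (median −0.28, camera adjusted p 0.00459, with an estimated correlation p 0.428, and −0.32 in block 3).

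Ageing of DBA/2J from 4 to 9 months asked what changes while the disease develops. The complement genes C3 and C4b, which label targets for phagocytes, rose, as did Serping1, a complement inhibitor, and Lcn2, an iron-binding protein of reactive glia. Fosb, Egr1, Fos and Zfp36, which respond early to activity and stress, and the antigen presentation genes B2m and H2-K1 rose too. Genes known from inhibitory amacrine cells that fell were the transcription factors Tfap2b and Tfap2a, the GABA-synthesising enzymes Gad1 and Gad2 and the vesicular transporter Slc32a1. Elavl4 and Nefm, genes of ganglion cells, the synaptic receptor Gria3 and the channel subunit Cacna2d1 fell with them. Of 13587 genes, 3044 passed, 1257 higher and 1787 lower at 9 months, so 41.3% were higher. The DESeq2 and edgeR fits placed 59.7% and 54.2% of their calls on the higher side. Within block 3, with 3 DBA/2J libraries at 9 months against 10 at 4 months, 35 genes passed, 29 higher and 6 lower, and 14 of these were among the 3044. With block as a covariate 8 genes passed. Of the genes that the rule names, only Gpnmb, Serping1 and Atf3 passed within block 3 and none passed with the covariate. Of the 3044 genes, 64.3% had the same sign within block 3, where their median change in the pooled direction was 0.08 against 0.64 pooled. With the age labels permuted inside block 3 and all fits repeated, the genes then called gave 65.0 ± 10.6% and 0.08 ± 0.06 (SD over permutations). In 58 and 54 of 100 labellings, the real one included, the share and the median were as large, so the shared signs as a whole are no more than shared libraries and the choice of genes give.

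C3 was at 8.16 ± 7.62 at 9 months against 0.670 ± 0.627 at 4 months (log2 fold change 2.16 ± 0.33, adjusted p 6.01e-05, block 3 1.495, adjusted p 0.0824), and all 25 libraries at 9 months exceeded the highest 4-month library of either strain (1.98). The lowest of the 25 did so only just, at 2.00. C4b rose from 2.19 ± 0.929 to 19.6 ± 23.1 (2.25 ± 0.35, block 3 1.30) and Lcn2 from 0.320 ± 0.434 to 5.83 ± 4.33 (2.15 ± 0.30, block 3 1.41), both with a block 3 adjusted p of 0.0824. Serping1 passed in the pooled libraries (1.51 ± 0.26, adjusted p 2.04e-04) and within block 3 (1.86 ± 0.38, adjusted p 0.0461), but without DBA/2J replicate 26 it had 1.13 in block 3 (adjusted p 0.546) and without replicate 28 an adjusted p of 0.0952. The complement list was higher (median 0.71, camera adjusted p 8.58e-04, with an estimated correlation p 0.101), with 7 higher and 1 lower of 13 past the threshold over all genes and over the list alone, and had 0.29 within block 3 (camera adjusted p 0.00186, with an estimated correlation p 0.169). Interferon response genes, including B2m (19.3 ± 9.99 to 44.4 ± 18.04, block 3 0.60), H2-K1 (10.7 ± 2.73 to 18.02 ± 5.80, block 3 0.73) and Gbp2 (block 3 0.45), were higher as a list (median 0.77, camera adjusted p 1.7e-07, with an estimated correlation p 0.102), with 13 of 17 past the threshold and 15 adjusted over the list alone, and had 0.60 within block 3 (camera adjusted p 6.5e-09, with an estimated correlation p 0.298). Immediate early genes had a median of 0.49 (camera adjusted p 1.51e-05, with an estimated correlation p 0.102), 8 of 13 past the threshold, and 0.48 within block 3. Egr1 rose from 32.7 ± 13.02 to 84.7 ± 43.4 (block 3 1.14, adjusted p 0.147) and Fosb from 1.18 ± 0.616 to 9.38 ± 6.38 (block 3 0.70), and the block 3 values of Zfp36 and Fos were 0.83 and 0.58. Gpnmb rose from 9.15 to 31.7 (1.60 ± 0.24, adjusted p 5.71e-05, block 3 1.44 ± 0.29, adjusted p 0.0438), and its block 3 call ended without replicate 26 (1.27, adjusted p 0.546) or replicate 28 (1.40, adjusted p 0.147). The cytokine receptor subunits Osmr (1.55, block 3 0.72) and Il6st (0.54, block 3 0.22) rose as well.

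Among genes chosen after their values were seen, Stat3, which relays cytokine signals, rose to 85.5 from 40.1 (0.86 ± 0.23, adjusted p 0.00798) and was the strongest call within block 3 (1.86 ± 0.17, adjusted p 3.52e-05). The acute phase genes A2m (4.06 ± 0.52, adjusted p 0.00524) and Serpina3n (3.65 ± 0.66, adjusted p 0.0430), the guidance factor Slit3 (3.44 ± 0.44), the homeobox gene Dlx3 (3.98 ± 0.53), the endothelin Edn2 (2.42 ± 0.44) and, named by the rule, the stress transcription factor Atf3 (2.40 ± 0.44) also rose within block 3. The pooled changes of A2m (1.31 ± 0.50, adjusted p 0.0563) and Dlx3 (0.94 ± 0.56, adjusted p 0.225) did not pass. DBA/2J replicate 26 had the highest values of A2m (329.8), Serpina3n (235), Slit3 (96.2) and Dlx3 (102). It also had the fewest reads of all 61 libraries (5133114), the lowest Glul (88.2) and the lowest median of Müller glia markers (10.3, with 24.7 and 41.5 in replicates 27 and 28). Leaving it out gave 5 genes within block 3, and leaving out replicate 27 or 28 gave 244 and 15. A2m, Stat3, Slit3 and Dlx3 passed in all 3 of these fits, with A2m between 3.15 and 4.84 and Stat3 between 1.57 and 2.23. Serpina3n and Edn2 passed in 2 of the 3 and Atf3 in 1.

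Amacrine cell genes were lower at 9 months in the pooled libraries. Tfap2b fell from 188 ± 135 to 21.5 ± 25.5 (log2 fold change −3.46 ± 0.52, adjusted p 6.28e-05), Gad1 from 54.0 ± 37.1 to 12.004 ± 16.7 (−2.71 ± 0.59), Gad2 from 125 ± 86.4 to 37.8 ± 53.5 (−2.61 ± 0.67) and Slc32a1 from 14.8 ± 10.8 to 3.48 ± 6.60 (−2.26 ± 0.47). Their values within block 3 were −1.36, −0.93, −0.89 and −0.83, none past the threshold, and Tfap2a had −2.63 pooled and −1.14 there. In block 1 the median of amacrine and horizontal cell markers was 0.131 to 2.48 in the 6 DBA/2J libraries and as low, 0.0493 to 2.45, in the 4 D2-Gpnmb+ libraries of the same age, against 10.5 to 26.5 and 13.4 to 31.9 in block 3. In block 2, Gad1 ran from 0.194 to 63.9 in the 16 DBA/2J libraries and was 83.7 and 10.8 in the 2 D2-Gpnmb+ libraries. The amacrine and horizontal cell list had a median of −1.75 (camera adjusted p 2.39e-07, with an estimated correlation p 0.102), with 7 of 10 past the threshold and 9 adjusted over the list alone, and −0.91 within block 3 (camera adjusted p 8.64e-05, with an estimated correlation p 0.633). Ganglion cell markers had a median of −0.75 (camera adjusted p 2.69e-05, with an estimated correlation p 0.102), with 8 of 19 past the threshold and 10 adjusted over the list alone, and −0.38 within block 3 (camera adjusted p 0.0762). Elavl4 fell from 8.51 ± 5.25 to 1.94 ± 2.37 (−1.84, block 3 −0.86), Nefm from 7.73 ± 9.30 to 1.46 ± 1.67 (−1.54, block 3 −0.85) and the transcription factor Ebf3 from 41.7 ± 37.7 to 5.03 ± 8.65 (−2.85, block 3 −0.29). The block 3 values did not pass, and in the pooled libraries Thy1 (−0.47), Rbpms (−0.31) and Sncg (0.26) did not pass. Ion channels of ganglion cells (median −0.82, camera adjusted p 2.65e-06, with an estimated correlation p 0.102, 12 of 17 past the threshold) and synaptic genes (−0.58, camera adjusted p 4.63e-07, with an estimated correlation p 0.102, 16 of 28, and 19 lower and 1 higher adjusted over the list alone) fell alongside. Their medians within block 3 were −0.37 and −0.15. The glutamate receptor subunits Gria3 (−2.49), Gria4 (−1.24) and Grik2 (−2.85), the potassium channel Kcnc2 (−2.29) and the calcium channel subunit Cacna2d1 (−1.26) fell, with block 3 values of −1.30, −1.33, −1.05, −1.46 and −0.65.

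Rod markers (median 1.03, camera adjusted p 1.57e-05, with an estimated correlation p 0.377, 6 of 17 past the threshold and 11 adjusted over the list alone) and microglia markers (1.35, camera adjusted p 4.46e-05, with an estimated correlation p 0.352, 9 and 11 of 11) rose with age in the pooled DBA/2J libraries. Within block 3 their medians were 0.03 and 0.00, and Ctss (2.70 pooled, −0.06 in block 3) and Csf1r (1.97 and 0.00) did not pass there. Müller glia markers such as Vim (1.07, block 3 0.06) and Clu (1.45, block 3 −0.13) rose in the pooled libraries (median 0.80, camera adjusted p 5.56e-05, with an estimated correlation p 0.377, 6 past the threshold and 7 of 15 adjusted over the list alone), and the list had the opposite sign within block 3 (−1.29, camera adjusted p 8.42e-05, with an estimated correlation p 0.633). Ribosomal protein genes (median 0.72, camera adjusted p 9.51e-22, with an estimated correlation p 0.332, 51 of 72) and nuclear-encoded oxidative phosphorylation genes (0.38, camera adjusted p 1.27e-08, with an estimated correlation p 0.377, 30 of 78) rose, with 61 and 33 adjusted over each list alone and block 3 medians of 0.14 each. Among genes of NAD metabolism, Nmnat2, the axonal NAD-synthesising enzyme, fell (13.4 ± 6.63 to 5.40 ± 4.58, −1.37 ± 0.35, adjusted p 0.00508, block 3 −0.42), as did Sarm1, the NAD-cleaving executor of axon degeneration (−0.41, block 3 −0.15). Nampt, the rate-limiting enzyme of NAD salvage, fell in the pooled libraries (−0.52 ± 0.16, adjusted p 0.0163) and was higher within block 3 (0.22 ± 0.15, adjusted p 0.649).

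**Figure D3:**
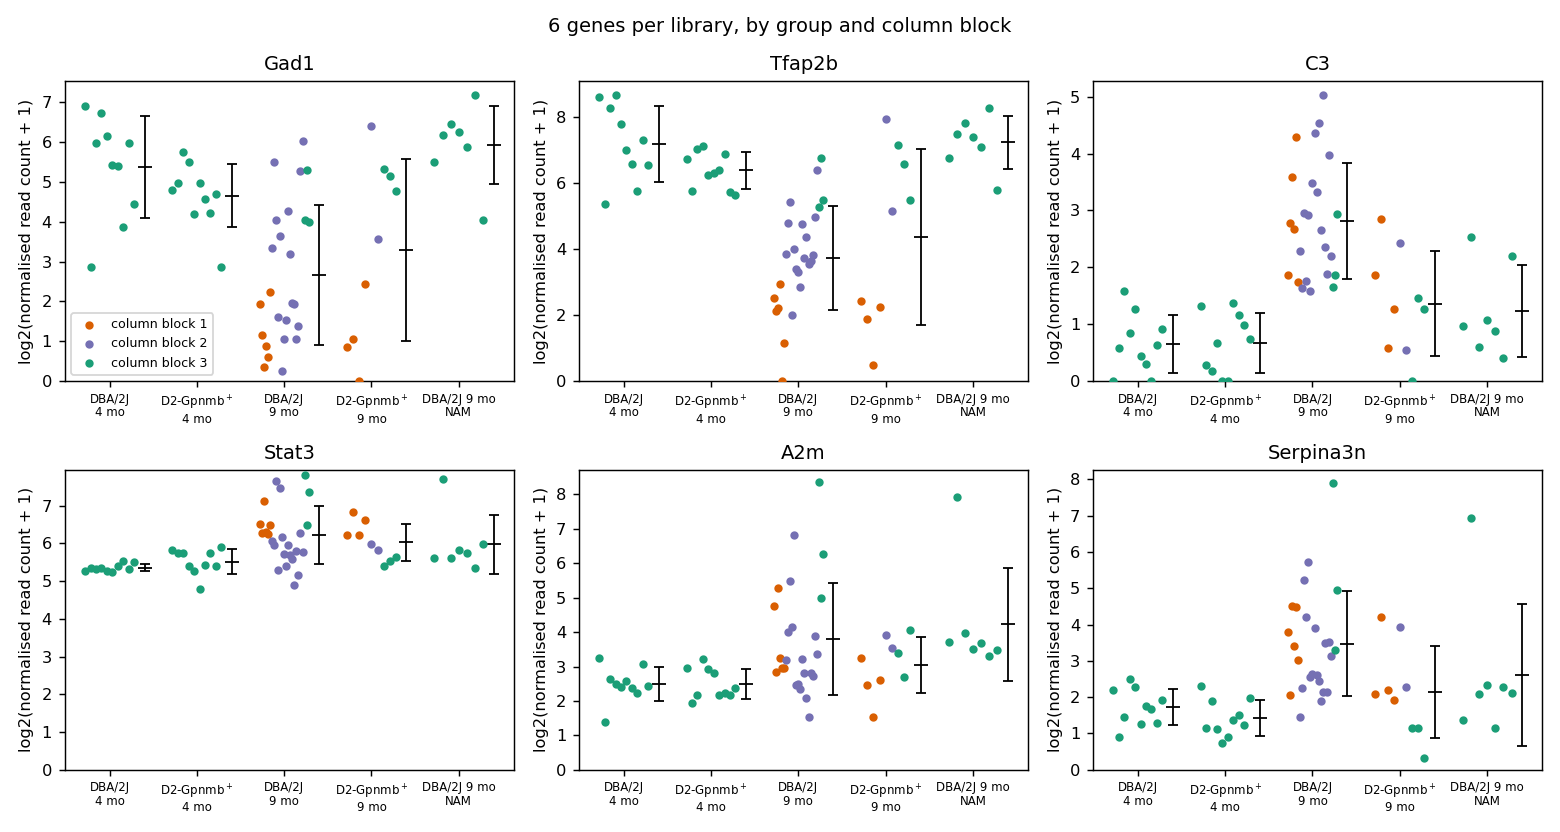
Each point is 1 library, as log2 of the deposited normalised read count plus 1, coloured by column block, with group mean and standard deviation. Gad1 and Tfap2b were low throughout block 1 and in part of block 2. C3 exceeded the highest 4-month value of 1.98 in all 25 DBA/2J libraries at 9 months, the lowest of which had 2.00 (NAM, nicotinamide).

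Ageing of D2-Gpnmb+ from 4 to 9 months served as the control without glaucoma. Adcy1, an adenylyl cyclase of neurons, fell from 249 ± 27.2 to 141 ± 35.4 (log2 fold change −0.86 ± 0.15, adjusted p 0.0382, block 3 −0.58). It was 1 of 3 genes past the threshold among 12910 tested, and the other 2, chosen here after their values were seen, were the gene models 2810047C21Rik1 (0.98, higher) and Gm5136 (−1.55, lower), both at an adjusted p of 0.0382. At an unadjusted p of 0.05, 3917 genes (30.3%) passed, and DESeq2 and edgeR called 2256 and 1501. The count was 2069 without D2-Gpnmb+ 9-month replicate 13, 1208 without replicate 15, 1065 without replicate 14 and 1010 without replicate 9, and 0 to 4 without any other library. Mitochondrially encoded oxidative phosphorylation genes were lower (median −1.79, camera adjusted p 2.46e-07, with an estimated correlation p 0.560, 13 of 13 adjusted over the list alone). Mitochondrial ribosomal RNA and Rn45s made up 23.1 ± 10.5% of reads at 9 months against 35.0 ± 9.40% at 4 months. Cone markers were lower too (median −1.07, camera adjusted p 4.51e-06, with an estimated correlation p 0.560, 9 of 10 alone). Müller glia markers (1.16, camera adjusted p 3.25e-07, with an estimated correlation p 0.560, 14 of 15 alone) and interferon response genes (0.86, camera adjusted p 1.99e-06, with an estimated correlation p 0.560, 11 of 15 alone) were higher. Rod markers were lower (−0.75, camera adjusted p 1.47e-04, with an estimated correlation p 0.561). Within block 3 these medians were 0.04, −0.05, −0.15, 0.23 and −0.54, so all 5 were smaller there and the mitochondrial and Müller glia medians changed sign. Gfap had 5.07 ± 3.71 against 0.995 ± 0.721, C4b 13.9 ± 12.9 against 1.73 ± 1.30 and Ifih1, a sensor of viral RNA, 9.41 ± 5.94 against 2.35 ± 1.49, each at an adjusted p of 0.0741. Scaling to total reads moved the median of all genes by 0.31 log2 in this comparison. Block 3 alone gave 0 genes by limma, with 605 at an unadjusted p of 0.05.

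The interaction of strain and age asked whether DBA/2J ages differently from D2-Gpnmb+. Gpnmb rose with age in DBA/2J relative to its control, Sox30, a transcription factor, and the ribosomal protein genes Rps21 and Rps27a rose too, and Pax6, a regulator of amacrine and ganglion cells, and the potassium channel Kcna2 fell. Of 14150 genes 53 passed, 18 with a higher and 35 with a lower change in DBA/2J. Gpnmb had an interaction of 2.31 ± 0.39 (adjusted p 0.00361, 2.08 with block as a covariate, 1.53 within block 3). Pax6 fell from 108 to 46.2 in DBA/2J and rose from 63.9 to 90.1 in D2-Gpnmb+ (−1.65 ± 0.35, adjusted p 0.0231, block 3 −1.55). Rps21 (1.58 ± 0.29, block 3 0.55), Sox30 (1.52, 1.39), Rps27a (1.24, 0.25) and the neuroendocrine vesicle gene Ptprn (1.11, 0.62) had the larger change in DBA/2J. Lrrn3 (−1.77, −0.87), Kcna2 (−1.64, −1.15), the splicing factor Rbfox2 (−1.58, −0.68), the matrix gene Ncan (−1.37, −0.90), Pag1 (−1.07, −0.57) and Aldh5a1 (−1.02, −0.55) had the lower. With block as a covariate 12 genes passed, all among the 53, with Gpnmb, Pax6, Rps21, Sox30, Pag1 and Aldh5a1 among them and Rps27a, Ptprn, Lrrn3, Kcna2, Rbfox2 and Ncan not. Of 29 pooled fits with 1 library left out, Gpnmb, Rps21, Pag1 and Aldh5a1 passed in all, Rps27a in 28 and Pax6 in 26. Kcna2 passed in only 10, Sox30 in 6, Ptprn and Rbfox2 in 5 each and Lrrn3 and Ncan in 4 each. Ribosomal protein genes had a median of 0.94 (camera adjusted p 1.63e-49, with an estimated correlation p 0.270), with 7 past the threshold and 64 of 72 adjusted over the list alone, and 0.19 within block 3. HIF1 target genes were the only list past the threshold with an estimated correlation within block 3 (median 0.32, camera adjusted p 2.39e-05, with an estimated correlation p 0.0387), a test added after the data were seen, and in the pooled libraries they did not pass (0.13, camera adjusted p 0.131). Rod markers had 1.70 (camera adjusted p 8.26e-17, with an estimated correlation p 0.311, 17 of 17 alone) and 0.62 within block 3. Amacrine and horizontal cell markers had −1.21 (camera adjusted p 2.77e-04, with an estimated correlation p 0.311) and −1.31 within block 3. Scaling to total reads moved the median of all genes by −0.36 log2 and gave 10 higher and 205 lower. The count of 53 became 239 without D2-Gpnmb+ 9-month replicate 9, 79 without DBA/2J 4-month replicate 10, 74 without D2-Gpnmb+ 9-month replicate 13 and 53 without its replicate 15, and lay between 9 (without DBA/2J 4-month replicate 1) and 33 without any other library of the 3 groups on water with 10 or fewer. Within block 3, 10 genes passed, all with the higher change in DBA/2J and none among the 53, including Stat3 (1.85 ± 0.26, adjusted p 9.00e-04), Serpina3n (4.198 ± 0.73), A2m (3.18 ± 0.60), Dlx3 (3.63 ± 0.59) and Slit3 (3.16 ± 0.55), chosen after their values were seen. In the pooled libraries these 5 had 0.35 (adjusted p 0.7098), 1.03, 0.76, 0.64 and 1.29, none past the threshold. As for age in DBA/2J, their block 3 errors come from a variance common to all groups. They can understate the spread of the 9-month DBA/2J libraries. Without single 9-month libraries the block 3 count was 110 without DBA/2J replicate 27 and 4 to 6 without any of the other 5. Stat3 and Dlx3 passed in all 6 of these fits, Serpina3n in 5, Slit3 in 4 and A2m in 2.

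Nicotinamide against water in DBA/2J at 9 months asked which changes the treatment alters. Gad2, Gad1, Tfap2b and Tfap2a, known from GABA-releasing amacrine cells, and Calb1, a calcium buffer of amacrine and horizontal cells, rose with nicotinamide. The channel genes Kcnc2 and Cacna2d1, the receptors for glial-derived factors Ret and Gfra1, the cone gene Gnat2 and the cholesterol synthesis genes Hmgcs1 and Fdft1 rose too. The complement gene C3, the interferon-inducible genes B2m and Ifitm3, the immediate early genes Fos and Egr1, and Gpnmb fell. Of 13925 genes 2105 passed, 1362 higher and 743 lower with nicotinamide, so 64.7% were higher. The edgeR, DESeq2 and total-read fits placed 50.5%, 39.9% and 78.4% of their calls on the higher side. Within block 3, with 7 nicotinamide and 3 water libraries, only Arap2 passed, a gene chosen here after its value was seen that controls small GTPases (1.27 ± 0.16, adjusted p 0.0140, pooled 0.44), and 2296 genes (16.5%) passed an unadjusted p of 0.05. Leaving out DBA/2J replicate 27 gave 391 genes there, and leaving out replicate 26 or 28 gave 2 and 0. With block as a covariate 0 genes passed. Of the 2105 genes, 72.4% had the same sign within block 3, where their median change in the pooled direction was 0.17 against 0.80 pooled. With labels permuted inside block 3 and all fits repeated, the genes then called gave 67.7 ± 8.81% and 0.09 ± 0.05 (SD over permutations), and 29 and 11 of 100 labellings, the real one included, gave values as large. The pooled count was 1294 without nicotinamide replicate 3, 1304 without replicate 7 and 1400 without replicate 4.

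Gad2 had 221 ± 115 with nicotinamide against 37.8 ± 53.5 (log2 fold change 3.62 ± 0.76, adjusted p 0.00164), Gad1 70.5 ± 39.7 against 12.004 ± 16.7 (3.26 ± 0.66), Tfap2b 168 ± 82.1 against 21.5 ± 25.5 (3.50 ± 0.59) and Calb1 13.3 ± 6.55 against 2.42 ± 2.35 (2.24 ± 0.39). Within block 3 these were 1.90, 1.48, 1.40 and 2.15, none past the threshold, and Tfap2a had 2.86 pooled and 1.36 there. The amacrine and horizontal cell list had a median of 2.40 (camera adjusted p 3.12e-09, with an estimated correlation p 0.0921), with 8 of 10 past the threshold over all genes and over the list alone, and 1.44 within block 3 (camera adjusted p 2.02e-06, with an estimated correlation p 0.706). Ion channels of ganglion cells had 0.83 (camera adjusted p 6.84e-07, with an estimated correlation p 0.0921, 11 of 17) and 0.58 within block 3 (camera adjusted p 0.00529, with an estimated correlation p 0.706). Ganglion cell markers had 0.80 (camera adjusted p 1.59e-05, with an estimated correlation p 0.0921, 8 of 20) and 0.43 within block 3 (camera adjusted p 0.0631). Elavl4 rose (1.86, block 3 0.87), as did Nefm (1.42, 0.73) and the nicotinic receptor subunit Chrnb3 (2.79, 1.13), while Thy1 (0.71), Rbpms (−0.02) and Pou4f1 (0.43) did not pass. Kcnc2 (2.81, block 3 1.98), Cacna2d1 (1.53, 0.92), the sodium channel Scn1a (2.53, 0.74), Ret (1.74, 1.46) and Gfra1 (1.71, 1.70) rose. Synaptic genes had a median of 0.46 (camera adjusted p 3.38e-06, with an estimated correlation p 0.165, 11 of 28 and 13 alone) and 0.12 within block 3. Cone markers had 1.01 (camera adjusted p 3.93e-05, with an estimated correlation p 0.243, 8 of 10 and 9 alone) and 0.41 within block 3, and the cone transducin Gnat2 rose from 201 ± 113 to 542 ± 124 (1.62, block 3 0.74).

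C3 fell from 8.16 ± 7.62 to 1.73 ± 1.73 (log2 fold change −1.58 ± 0.40, adjusted p 0.00663, block 3 −0.91). The complement list had a median of −1.06 (camera adjusted p 0.0154, with an estimated correlation p 0.165), with 5 lower and 1 higher of 13 past the threshold, 8 and 1 adjusted over the list alone, and −0.34 within block 3 (camera adjusted p 0.145). B2m (−1.40, block 3 −0.81), Gbp2 (−1.27, −0.68) and Ifitm3 (−1.93, −1.59) fell, and the interferon response list had −0.55 (camera adjusted p 0.00102, with an estimated correlation p 0.375, 2 of 18) and −0.43 within block 3 (camera adjusted p 9.32e-04, with an estimated correlation p 0.706). Immediate early genes had −0.81 (camera adjusted p 1.85e-06, with an estimated correlation p 0.0921, 8 of 14 and 9 alone) and −0.56 within block 3 (camera adjusted p 9.32e-04, with an estimated correlation p 0.696). Fos fell from 31.3 ± 12.99 to 11.4 ± 5.69 (block 3 −0.97) and Egr1 from 84.7 ± 43.4 to 33.8 ± 11.4 (block 3 −1.06). Gpnmb fell from 31.7 ± 16.4 to 11.8 ± 3.35 (−1.23 ± 0.27, adjusted p 0.00204, block 3 −1.07 ± 0.23, adjusted p 0.0832). Hmgcs1 (0.81 ± 0.16, block 3 0.83) and Fdft1 (0.72, 0.82) rose, and the cholesterol and fatty acid synthesis list had 0.27 in the pooled libraries (camera adjusted p 0.187) and 0.60 within block 3 (camera adjusted p 3.09e-07, with an estimated correlation p 0.696). Nampt rose in the pooled libraries (0.58 ± 0.18, adjusted p 0.0296) and was −0.17 within block 3, and Nmnat2 rose from 5.40 ± 4.58 to 12.5 ± 4.07 (1.37 ± 0.40, adjusted p 0.0177, block 3 0.41). Microglia markers (median −1.38, camera adjusted p 1.21e-04, with an estimated correlation p 0.384, 3 of 12 and 12 alone) and ribosomal protein genes (−0.56, camera adjusted p 3.21e-14, with an estimated correlation p 0.375, 28 of 72 and 42 alone) were lower, with 0.00 and −0.03 within block 3. Müller glia markers were lower in the pooled libraries (−0.91, camera adjusted p 1.95e-05, with an estimated correlation p 0.372, 5 of 15 and 11 alone) and higher within block 3 (0.92, camera adjusted p 9.32e-04, with an estimated correlation p 0.706). Rod markers did not pass in the pooled libraries (−0.26, camera adjusted p 0.269) and were higher within block 3 (0.59, camera adjusted p 3.09e-07, with an estimated correlation p 0.706). Bipolar markers had 0.12 (camera adjusted p 0.361) and −0.25 within block 3 (camera adjusted p 0.0215, with an estimated correlation p 0.742). Endothelial and pericyte markers were lower in both (−0.80, camera adjusted p 3.88e-04, with an estimated correlation p 0.375, and −0.67 within block 3). The acute phase genes Stat3 (73.5 against 85.5, adjusted p 0.637), A2m (44.5 against 31.7, adjusted p 0.693) and Serpina3n (19.8 against 21.3, adjusted p 0.364) did not pass, and their means rest on nicotinamide replicate 2. It had 207, 243 and 121, against at most 62.8, 14.7 and 4.01 in the other 6, and the lowest Glul of its group (181, against 541 to 955). Without it the log2 fold changes were −0.53, −0.19 and −1.58, and without single others they reached −0.14, 0.58 and −0.61, so the direction of A2m depends on that library. These 3 genes were chosen after their values were seen.

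**Figure D4:**
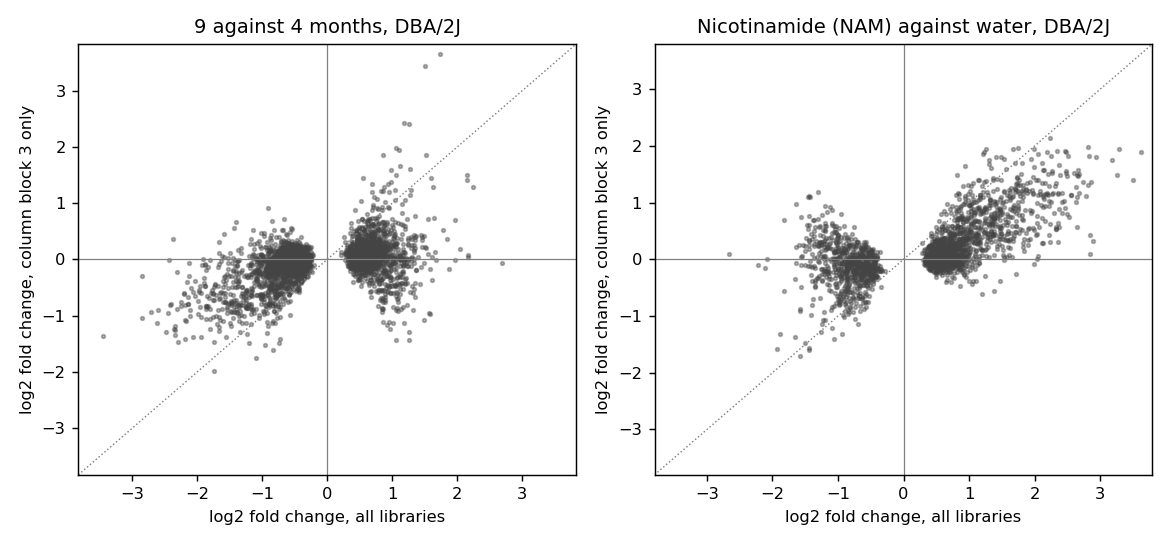
Each point is 1 gene past the threshold in the pooled libraries, with its pooled log2 fold change on the horizontal axis and its log2 fold change within block 3 on the vertical axis. Of 3044 genes for age (left) and 2105 for nicotinamide (right), 14 and 0 also passed within block 3. The 2 axes share libraries and the genes were chosen on the pooled values, so a slope does not show replication.

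Nicotinamide-treated DBA/2J against D2-Gpnmb+ at 9 months asked how far treated animals differ from controls without disease. Strain and treatment differ together here, and within block 3 the groups also lie in separate stretches of columns. Strain, treatment and column order therefore cannot be told apart. None of 13054 genes passed by limma, with 3838 (29.4%) at an unadjusted p of 0.05, while DESeq2 called 2254 and edgeR 1060. Gpnmb had 11.8 ± 3.35 against 54.2 ± 24.1 (log2 fold change −1.98 ± 0.32, adjusted p 0.0594). Within block 3 40 genes passed, 13 higher and 27 lower, and Gpnmb was the strongest (−2.60 ± 0.20, adjusted p 6.77e-06, 11.8 against 74.7 ± 8.19). The neurofilament Nefm (4.63 ± 1.12 against 1.24 ± 0.236, 1.31, adjusted p 0.0221) and Stmn2, a tubulin-binding protein of growing axons (1.26, adjusted p 0.0488), were higher, as was Dcx (1.47), a microtubule protein of young neurons. The hypoxia-inducible genes Higd1a (0.73) and Ndrg1 (0.86) and the adrenergic receptor Adra2a (1.86) were higher, and the synaptic scaffolds Shank1 (−0.59) and Shank2 (−0.58) and the glutamate receptor Grm5 (−0.73) were lower. Apart from Gpnmb, Nefm and Stmn2, these genes were chosen after their values were seen. In the pooled libraries, where none passed, Nefm had 1.59, Stmn2 1.09, Dcx 1.97, Higd1a 1.52, Ndrg1 0.25, Adra2a 1.49, Shank1 0.08, Shank2 −0.18 and Grm5 0.08. Leaving out D2-Gpnmb+ replicate 13 or 14 gave 3 genes within block 3, and leaving out replicate 15 gave 296. Of the genes named here only Gpnmb passed without replicate 13 or 14, and Nefm had an adjusted p of 0.0870 and 0.116 and Stmn2 of 0.123 and 0.171. Glycolysis genes such as Pgam1, Ldha and Pgk1 were higher as a list (0.41, camera adjusted p 0.00601, with an estimated correlation p 0.583, 9 higher and 1 lower alone) and within block 3 (0.30, camera adjusted p 2.06e-05, with an estimated correlation p 0.497). Axon transport and cytoskeleton genes were higher as well (0.57, camera adjusted p 3.71e-06, with an estimated correlation p 0.536, 10 of 23 alone, and 0.24 within block 3). Amacrine and horizontal cell markers had 1.98 (camera adjusted p 5.65e-04, with an estimated correlation p 0.536) and 0.72 within block 3, and rod markers 0.92 (camera adjusted p 5.96e-05, with an estimated correlation p 0.583) and 0.74. Müller glia markers had −1.37 (camera adjusted p 3.71e-06, with an estimated correlation p 0.536, 13 of 15 alone) and −0.16 within block 3. The pooled count was 1537 without D2-Gpnmb+ replicate 13, 365 without replicate 15 and 184 without replicate 9, and lay between these without replicate 8.

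Nicotinamide-treated DBA/2J at 9 months against untreated DBA/2J at 4 months, a comparison added after the data were seen, lies wholly within block 3. Age and treatment differ together in this comparison, and the nicotinamide columns precede all water columns in that block. Age, treatment and column order therefore cannot be told apart. The phosphodiesterase Pde10a, the contractile protein gene Myh11 and the matrix gene Ecm2 fell, and Calb1 and the transcription factor Onecut3, genes of horizontal cells, rose. Of 17 fits with 1 library left out, these passed in 17, 17, 15, 14 and 13. The contractile genes Acta2 and Myl9 and the matrix gene Bgn fell too but passed in only 4 of the 17 each. Of 13024 genes 200 passed, 103 higher and 97 lower, with 16 without nicotinamide replicate 5, 19 without replicate 3, 413 without replicate 8 and 349 without DBA/2J 4-month replicate 3. Calb1 had 13.3 ± 6.55 against 3.98 ± 2.06 (log2 fold change 1.51 ± 0.32, adjusted p 0.0273) and Onecut3 5.77 ± 3.05 against 1.85 ± 1.53 (1.32 ± 0.29). Rdh9 (1.24, 15 of 17 fits), Sox30 (0.97, 8), Dcx (1.17, 6) and the potassium channel Kcnj2 (1.06, 4) also rose, as did H2-D1, an antigen presentation gene (18.2 ± 4.00 against 11.2 ± 2.58, 0.65 ± 0.14, adjusted p 0.0261). Pde10a fell from 75.6 ± 14.97 to 32.6 ± 10.5 (−1.23 ± 0.17, adjusted p 0.00724), as did Myh11 (−1.40 ± 0.25), Acta2 (−1.16 ± 0.29), Ano3 (−0.94) and the amine oxidase Aoc3 (−0.84). Rod markers had a median of 0.65 (camera adjusted p 3.23e-16, with an estimated correlation p 0.274, 3 of 17 and 17 alone) and cone markers 0.59 (camera adjusted p 2.53e-09, with an estimated correlation p 0.247, 2 of 10 and 8 alone). Endothelial and pericyte markers had −0.55 (camera adjusted p 2.75e-05, with an estimated correlation p 0.436, 1 of 12 and 6 alone) and bipolar markers −0.37 (camera adjusted p 1.32e-05, with an estimated correlation p 0.425, 1 of 14 and 7 alone). Gpnmb (11.8 against 9.15, adjusted p 0.441), Nampt (96.6 against 94.0) and Nmnat2 (12.5 against 13.4) did not pass.

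The spread between libraries within a group was compared because disease in DBA/2J progresses at different rates in different eyes. The root mean square distance of a library from the mean of the rest of its group was 0.487 ± 0.110 log2 units in 9-month DBA/2J on water, 0.239 ± 0.0653 in 4-month DBA/2J and 0.285 ± 0.0826 in 4-month D2-Gpnmb+ (permutation tests, adjusted p 1.96e-07 and 1.49e-05). With nicotinamide it was 0.212 ± 0.0490 (adjusted p 5.94e-07, permutation test), and in 9-month D2-Gpnmb+ it was larger, at 0.601 ± 0.102 (adjusted p 0.0107, permutation test). The 9-month water groups are the only ones drawn from all 3 blocks. Within block 3 the differences from 9-month DBA/2J were 0.0961 (adjusted p 0.119), 0.0520 (adjusted p 0.346) and 0.126 (adjusted p 0.0333) for the first 3 groups and 0.0941 (adjusted p 0.267) for 9-month D2-Gpnmb+, by exact permutation tests. With distances taken within group and block, 9-month DBA/2J had the larger spread in all 4, by 0.154 (adjusted p 2.68e-04), 0.110 (adjusted p 0.00618) and 0.184 (adjusted p 2.68e-04) for the first 3 groups and by 0.0933 (adjusted p 0.0145) for 9-month D2-Gpnmb+, the reverse of the pooled order (permutation tests). These permutations did not hold the block fixed. Block 2 holds 16 of the DBA/2J libraries, 2 of 9-month D2-Gpnmb+ and no library of the other groups, so these p values mix block with group. Within block 1 the difference from 9-month D2-Gpnmb+ had the other sign, −0.0414 (adjusted p 0.0714, exact permutation test).

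The nicotinamide difference was set against the strain difference at 9 months and, as an addition after the data were seen, against the age difference in DBA/2J, across genes, which are not independent replicates. The shared water libraries alone gave simulated correlations of −0.242 and −0.249. The simulations drew each gene and library independently and so do not carry the correlation between genes. A value beyond the simulated one therefore does not by itself show an effect. With the strain difference, Pearson's r was −0.223 over 13703 genes (Spearman −0.177), with a covariance of −0.0386 against −0.0144 simulated. Splitting the water libraries at random gave r −0.152 ± 0.138 (SD, 100 splits). With the age difference r was −0.886 over 13578 genes (Spearman −0.859, covariance −0.219 against −0.0115 simulated) and −0.786 ± 0.0327 with split water libraries. When the age difference used water libraries of blocks 1 and 2 and the nicotinamide difference those of block 3, r was −0.0990 (Spearman 0.0345), and with block 3 libraries alone in both, which share their 3 water libraries, it was −0.782 against −0.733 simulated with no effect (covariance −0.105 against −0.0434). The same settings for the strain difference gave −0.263, and −0.662 against −0.594 simulated (covariance −0.0946 against −0.0404).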

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

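Tests of the ganglion cell markers and the splits of block 1 were written only after the result was seen, and all other tests of this part were written before their result, though the comparison of nicotinamide with 4 months was itself added after the data were seen.

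A library far from the rest of its group was flagged in 10 of 68 groups of values tested. A rate of about 1 in 20 by chance holds only for normally distributed values, which read counts need not be. No excess over chance is therefore read from this count. Groups of more than 10 libraries were not tested, so 9-month DBA/2J on water is not covered. Nicotinamide replicate 2 had the highest value of its group for Stat3 (207), A2m (243), Serpina3n (121) and Gfap (42.7), genes of reactive glia and cytokine signalling. These flags all come from 1 library, and Stat3, A2m and Serpina3n were chosen after their values were seen. The median of the rod markers was 586 in D2-Gpnmb+ at 9 months replicate 9. Thy1 was 84.1 in nicotinamide replicate 7, and Gad1 was 83.7 in D2-Gpnmb+ at 9 months replicate 8. Gfap was 4.03 in DBA/2J at 4 months replicate 10. The median of the microglia markers was 0.0863 in DBA/2J at 4 months replicate 1 and 0.0619 in D2-Gpnmb+ at 4 months replicate 2. The rest of each of these groups had 0, so any value above 0 is flagged by construction and these 2 decide nothing. Without such groups 8 of 66 were flagged. The interaction of strain and age was flagged because 53 genes passed its test in the pooled libraries, with a log2 fold change of 2.31 for Gpnmb. With block as a covariate 12 of them passed and within block 3 none did.

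Random splits into groups of the same sizes bear on whether chance can be excluded, and the real grouping counts as 1 of the 100 splits. Splits with as many genes as the real grouping numbered 1 for strain at 9 months (real 3, highest other 1), 1 for strain at 4 months (32 and 17), 1 for age in DBA/2J (3044 and 105) and 1 for age in D2-Gpnmb+ (3 and 0). They numbered 1 for the interaction (53 and 12), 1 for nicotinamide (2105 and 141), 1 for strain inside block 1 (1635 and 140) and 2 for nicotinamide against 4 months (200 and 298). For nicotinamide against D2-Gpnmb+ the real count was 0, which all 100 splits reach by construction, so that number decides nothing. The splits do not hold the column block fixed, so the counts for strain at 9 months, age, the interaction and nicotinamide can still come from blocks. The highest split gave 2840 genes, which points to a structure of the libraries other than the 2 groups.

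Gad1, Gad2 and Tfap2b were higher and C3, Fos and Egr1 lower with nicotinamide, among 2105 genes past the threshold in the pooled libraries. Of these, 89.7% had the same sign in block 3 against blocks 1 and 2 of D2-Gpnmb+ at 9 months, libraries that received no nicotinamide (highest other split 90.6%, 3 of 84 splits as large). In that contrast of 3 and 6 libraries only 1 of 13654 genes passed the threshold, so the signs and not single calls are used. A difference between column blocks could therefore give most of the signs without an effect of nicotinamide. RNA of amacrine cells, which the sort on Thy1.2 does not exclude, was the other explanation, and the median signed correlation with amacrine markers inside group and block was 0.140 (permuted SD 0.0615), which cannot tell. An effect of nicotinamide is not excluded and can be separated from the blocks only inside block 3, where 7 treated and 3 water libraries gave 1 gene, with 2296 at an unadjusted p of 0.05. There the treated columns form 1 stretch before all water columns, so column order cannot be told apart from treatment.

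Inside block 1, 1635 genes differed between the strains. Of these, 54.3% had the same sign in blocks 2 and 3 (permuted mean 50.1%, SD 17.6), with 32.7% in block 2 and 70.6% in block 3, so batches of libraries inside block 1 could not be told from a strain difference. RNA of rods, also not excluded by the sort, gave a median signed correlation of 0.175 (permuted SD 0.123), which cannot tell. Marker medians separated the strains completely in block 1, with rod markers at 23.5 to 195 in D2-Gpnmb+ and 208 to 350 in DBA/2J, cone markers at 28.3 to 66.7 and 101 to 206, and Müller glia markers at 325 to 557 and 132 to 319. Cell composition was thus not excluded as a source of the difference.

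Ganglion cell markers such as Thy1, Rbpms and Pou4f1 lay far below rod and bipolar markers. Of 5 lists of other retinal cell types, 4 had a median above the ganglion cell list in every library. That count restates the pattern, that marker RNA of other types lay above that of ganglion cells, and cannot test its source. Whether it came from cells of these types or from their RNA alone stays open. Loss of ganglion cells with disease would leave young D2-Gpnmb+ libraries unaffected, and there the highest log2 ratio of ganglion cell to bipolar markers was −5.94 (mean −6.68, n = 10), so that explanation was not borne out.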

How the results depend on the processing

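Tests of column blocks, scaling to total reads, pseudocounts and edgeR were chosen only after the result was seen, as was the comparison of nicotinamide against 4 months.

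Gpnmb at 4 months (−3.19 to −2.95) and in age of DBA/2J (1.48 to 1.68) kept direction and side of the threshold in the pooled fits with single libraries left out. Only libraries of groups of 10 or fewer were left out, so the 25 of DBA/2J on water at 9 months never were in the pooled fits, and inside block 3 the age call of Gpnmb ended without replicate 26 or 28. The sample number series was not used as a setting of its own, because column names match groups and not samples. The order of groups along the sample numbers equals that along all 61 columns, so the blocks are the series if columns follow these numbers. No library was shallow enough to be left out (0 of 61), and no paired analysis was possible because groups share no sample numbers. Depth limits genes of few reads, and where a value changed the cause was not tested.

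Counts for strain at 9 months were 9 with a filter at 10 in place of 1 and with edgeR, 332 with DESeq2, 79 with voom, 680 with all groups in 1 fit and 1635 in block 1 alone. They were 0 with total reads, rod markers or Xist as covariate, with pseudocount 5, with scaling to total reads and in block 3. For strain at 4 months they were 247 (DESeq2), 86 (voom), 2 (all groups), 69 (total reads covariate), 13 (rod markers), 19 (Xist) and 20 (scaling). Age in DBA/2J gave 5854 (voom), 8 (block covariate) and 35 (block 3). Age in D2-Gpnmb+ gave 2256 (DESeq2), 1 (voom, rod markers), 1653 (all groups), 1501 (edgeR) and 0 (total reads, Xist, scaling, block covariate, block 3). The interaction gave 81 (filter at 10), 298 (DESeq2), 593 (voom), 146 (all groups), 1 (rod markers), 9 (Xist), 20 (pseudocount 0.1), 215 (scaling), 12 (block covariate) and 10 (block 3). Nicotinamide gave 6115 (voom), 0 (block covariate) and 1 (block 3). Nicotinamide against D2-Gpnmb+ gave 2254 (DESeq2), 6 (voom), 1678 (all groups), 3 (rod markers), 8 (Xist), 1060 (edgeR), 2 (scaling), 1 (block covariate) and 40 (block 3). Nicotinamide against 4 months gave 501 (DESeq2), 514 (voom), 0 (all groups), 30 (total reads), 2 (rod markers) and 15 (Xist). With single libraries of the groups of 10 or fewer left out the ranges were 0 to 55, 6 to 92, 0 to 2069, 9 to 239, 1294 to 1861, 0 to 1537 and 16 to 413 for strain at 9 and 4 months, age in D2-Gpnmb+, interaction, nicotinamide, nicotinamide against D2-Gpnmb+ and nicotinamide against 4 months.

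No list passed with an estimated correlation (0 in all comparisons), and within block 3 with it 1 did for the interaction and 0 for the other comparisons. Lists called were 8 for age in D2-Gpnmb+ with block 3 or the block covariate, 10 and 11 for nicotinamide, and 11 for nicotinamide against D2-Gpnmb+ with rod markers. In block 3 these values had the other sign, and where the block covariate also reversed them it gave the same value. Age in DBA/2J: Ctss −0.0607, Csf1r −0.00218, Clu −0.13, Nampt 0.22, Müller glia −1.29, HIF1 targets 0.13, fatty acid oxidation −0.14 and axon transport 0.0481. Age in D2-Gpnmb+: bipolar 0.13, Müller glia −0.15, endothelial −0.20, nuclear oxidative phosphorylation 0.0755, mitochondrial 0.0443, synaptic 0.0890, ion channels 0.24 and axon transport 0.0606. Nicotinamide: Nampt −0.17, rod 0.59, bipolar −0.25, Müller glia 0.92, fatty acid oxidation 0.0480 and axon transport −0.0288. Nicotinamide against D2-Gpnmb+: Shank1 −0.59, Grm5 −0.73, bipolar −0.33, nuclear oxidative phosphorylation −0.0297, mitochondrial −0.83, cholesterol synthesis 0.24, fatty acid oxidation 0.12 and interferon 0.20. Strain at 9 months: endothelial 0.10 (0.00172 with the covariate), mitochondrial −0.64 and ribosomal −0.0524. The interaction of interferon genes was 0.45. Spread differences were 0.0961, 0.0520 and 0.0941 in block 3, −0.0414 in block 1 and 0.0933 within group and block, the 0.0941 (adjusted p 0.267) and 0.0933 (adjusted p 0.0145) with the other sign. The permutations behind the 0.0933 did not hold the block fixed. The correlation of nicotinamide and strain was −0.662 in block 3 (−0.594 simulated with no effect). Over the 3 called genes it was −0.956, which decides nothing, since they were chosen by 1 of the contrasts and number only 3.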

Other observations

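The only tests added in this part are those between column blocks, chosen after the data were seen, and the genes were chosen after their values were seen.

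Complement and acute phase genes stood above young levels in different numbers of libraries at 9 months. C3 exceeded the highest 4-month library of either strain in 25 of 25 DBA/2J libraries on water, 3 of 9 D2-Gpnmb+ libraries and 2 of 7 nicotinamide libraries, and C4b in 22, 5 and 3. Lcn2, a protein of reactive glia, did so in 24, 3 and 3, Serping1 in 19, 4 and 1, and Atf3, a transcription factor of injured neurons, in 16, 2 and 1. For Serpina3n the numbers were 18, 2 and 1, for Edn2, an endothelin, 18, 1 and 5, for Slit3 16, 1 and 3, and for Stat3 16, 5 and 2. A2m was above the young range in 11, 4 and 7, Gfap in 13, 6 and 1, H2-D1 in 12, 1 and 5 and Dlx3 in 9, 1 and 1. The lowest C3 of the 25 DBA/2J libraries was 2.00, only just above the young range, which ended at 1.98. All 4-month and nicotinamide libraries lie in column block 3, so only its 3 DBA/2J and 3 D2-Gpnmb+ libraries of 9 months on water share a block with them. There 3 of 3 DBA/2J libraries on water were above for 9 of the 13 genes and 2 of 3 for C4b, Atf3, Serping1 and Gfap. Stat3, Slit3, Dlx3, A2m, H2-D1, Atf3, Edn2, Serpina3n and Serping1 were age calls of DBA/2J within block 3, from these same libraries. For them the DBA/2J counts in block 3 follow from that choice and add no support. Of the 3 D2-Gpnmb+ libraries 2 were above for A2m, 1 for Edn2, 1 for Gfap and 0 for the other 10 genes. In blocks 1, 2 and 3 of DBA/2J, Atf3 was above in 1 of 6, 13 of 16 and 2 of 3 libraries and Stat3 in 6 of 6, 7 of 16 and 3 of 3.

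Libraries of 1 group also differed between column blocks. In 9-month DBA/2J on water, limma called 3664 genes between blocks 1 and 2, 665 between blocks 2 and 3 and 4325 between blocks 1 and 3. In 9-month D2-Gpnmb+ it called 5431 between blocks 1 and 3. The blocks were drawn after these same expression values were seen, in which the columns of block 1 stood apart. The counts that involve block 1 therefore restate that choice and are not separate evidence of a difference between blocks. The 665 between blocks 2 and 3 do not involve block 1, though that division too was made after the values were seen. Gpnmb in DBA/2J had 18.8 ± 8.62, 37.6 ± 17.1 and 25.6 ± 6.66 in blocks 1, 2 and 3, and in D2-Gpnmb+ 34.8 ± 15.4, 62.3 ± 29.98 and 74.7 ± 8.19.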
